A study of Mus musculus with 2 samples.

How the data were processed

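Trimethylation of histone H3 at lysine 4 (H3K4me3), a mark found mainly at the promoters of genes, was profiled by chromatin immunoprecipitation and sequencing in mouse limb tissue of embryonic day 14.5. Per the labels, 2 biological replicates were made, from pools of 24 and 34 embryos of both sexes, and both form 1 group. No second tissue, stage or treatment was compared, so no test between groups was made. The comparisons are those between the replicates and those between sets of genes within the tissue.

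The values analysed are 4 deposited peak lists on the mm10 assembly. Per the text deposited with the samples, the first list holds the peaks of replicate 1, the second those of replicate 2, the third those of both replicates pooled, and the fourth is the replicated list, derived from the pooled list and both replicates' own lists. For each peak the authors deposited a fold enrichment (a ratio), a -log10 p-value and a -log10 q-value. The peak caller, the aligner, the rule by which a peak counted as replicated and the composition of the background are not given in the sources used here. The highest deposited p-value was 0.00737 in replicate 1 and 0.00891 in replicate 2. The input control was not used here. No read counts were used, so the depth per replicate is unknown and no interval that needs it is given; intervals for shares of peaks or genes are 95% Wilson intervals and treat peaks or genes as independent, which they are not.

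Gene positions were those of GENCODE release M21, whose assembly (GRCm38) is that of mm10. No peak extended past the end of its chromosome in the reference. Peaks on scaffolds outside the assembled chromosomes, 12 of the replicated list, were left out of the domain counts. A TSS window was 1 kb on either side of any annotated transcription start site (TSS) of a gene. A gene had a TSS domain if a peak of the replicated list overlapped its window by at least 1 bp. Peaks no more than 1 kb apart were joined into domains. The width of a gene's domain was that of its widest domain in a replicate's own list, limited to peaks that overlap a replicated peak, averaged over the replicates; a gene without a domain counted as width 0. The fold enrichment of a gene was the highest of the peaks at its windows in each replicate. Promoter CpG observed/expected was counted in the 500 bp on either side of each TSS, taking the highest value per gene, and the 21938 protein-coding genes were split into 10 deciles.

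Before the data were examined, 20 gene lists with 296 genes and 11 gene families were fixed: 10 lists for tissues of a limb, 7 for organs that a limb lacks and 3 controls. All symbols were found in the annotation. For each list, the median width and the share with a domain were set beside 10000 random lists of the same size matched on CpG decile, and the result is a percentile, which describes these libraries and is not a p-value. A list is called high at or above the 97.5th percentile and low at or below the 2.5th. The limb lists together and the other organ lists together were compared with 10000 random reassignments of their genes. Overlap between lists was set beside 100 random circular shifts along each chromosome. The genes named are the 20 with the widest domain and the 10 with the highest fold enrichment, the 3 widest members of each list and up to 4 members without a domain in alphabetical order, Tbx5, Tbx4, Pitx1, Shh, Hoxa13, Hoxd13, Sox9 and Myod1, the Hox clusters, the 5 genes in each direction with the largest width ratio between replicates among genes with at least 1 kb in both, and the 5 widest domains with no TSS window within 5 kb. Genes that share a domain are named together. Other genes named were chosen after their values were seen.

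The alternatives were a threshold on q (at most 0.05, or -log10 q of at least 5), the pooled list or loci in both replicates' own lists, each replicate alone, TSS windows of 500 bp and 2 kb, the most upstream TSS only, joining distances of 0 bp and 3 kb, random lists without matching, fold enrichment instead of width, no limit to replicated loci, an overlap of at least 50% of the peak or of both peaks, and the widest 10% or 2% of domains. The alternatives with each replicate alone (without replicate 1 or 2) took that replicate's own list in place of the replicated list. They thus also dropped the limit to replicated loci. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. On simulated intervals the overlap and joining steps gave the same result as bedtools 2.31.1, with 0 differences. On widths simulated for the 21938 genes, 2.5% of 200 unchanged lists of 20 genes were called high, 22.0% of lists with widths raised 1.5-fold, 43.5% with 2-fold and 50.0% with 3-fold. In simulated comparisons of 156 with 90 genes, 3 of 100 without and 26 of 100 with a 2-fold difference were called high. Both comparisons thus missed many simulated differences. In the simulation 11410 of the 21938 genes had a domain, against 14569 in the data. A median of 0 bp cannot be raised by multiplying widths, so these rates need not hold for the lists here. How many real differences are missed is not known.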

Results

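H3K4me3 was mapped in mouse limb tissue at embryonic day 14.5 in 2 replicates, pools of 24 and 34 embryos. The tissue holds cartilage, connective tissue, muscle, skin, vessels and blood, and the labels do not separate fore from hind limbs. Replicate 1 gave 26903 peaks over 35.5 Mb and replicate 2 gave 28700 peaks over 36.4 Mb, with median widths of 1070 and 969 bp. The pooled list held 28448 peaks and the replicated list 22488 peaks over 38.5 Mb, or 1.41% of the reference chromosomes, with a median width of 1530 bp. Fold enrichment, the authors' value for each peak, had a median of 14.4 in replicate 1 and 12.3 in replicate 2 and reached 74.1 and 76.8.

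The replicates shared most peaks. Of the peaks of replicate 1, 87.4% (95% interval 86.97 to 87.8%) overlapped a peak of replicate 2, and of those of replicate 2, 81.9% (81.5 to 82.4%) overlapped a peak of replicate 1. After random shifts the shares were 2.72% and 2.58% on average, and at most 3.24% and 2.997%. The peaks without a partner were weak and narrow, with a median fold enrichment of 3.14 and 3.15 and median widths of 240 and 239 bp, against 21.1 and 22.4 and 1307 and 1323 bp for the shared ones. Across 14473 genes with a TSS domain in both replicates, fold enrichment correlated with a Pearson's r of 0.92 on the log2 scale and a Spearman's rho of 0.82, and width with an r of 0.95 on the log2 scale. The widths were limited to replicated loci, and without that limit the r of width was 0.93. These correlations are across genes within a pair of samples, genes are not independent replicates, and no p-value is given.

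Most protein-coding genes carried the mark at a TSS. A TSS domain was found at 14569 of 21938 protein-coding genes, or 66.4%, and in the replicates' own lists at 66.5% and 66.8%. The share was 0.684% among the genes with the lowest promoter CpG content and 99.6% among those with the highest. Receptor genes of the nose were nearly all without the mark: 1 of 1135 olfactory receptor genes, Olfr94, and 1 of 331 vomeronasal receptor genes, Vmn1r4, had a domain, and that of Vmn1r4 also covered the TSS window of Nt5c3. CpG-matched random lists had 6.24% on average for the olfactory genes (percentile 0) and 2.75% for the vomeronasal genes (0.015th percentile). None of 64 defensin genes, which encode antimicrobial peptides, had a domain, while CpG-matched random lists had 4.62% on average. Among keratin genes 12 of 49 had a domain (24.5%, 0.07th percentile of matched lists). Ribosomal protein genes had a domain in 80 of 83 cases, or 96.4% against 98.0% in matched lists (11.7th percentile, no call). Zinc finger genes with Zfp symbols had one in 323 of 365, or 88.5% against 80.3% (percentile 100). Of other gene types, 15.2% of 5854 lincRNA genes and 35.5% of 2959 antisense RNA genes had a domain, against 1.89% of 9940 processed pseudogenes.

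**Figure D1:**
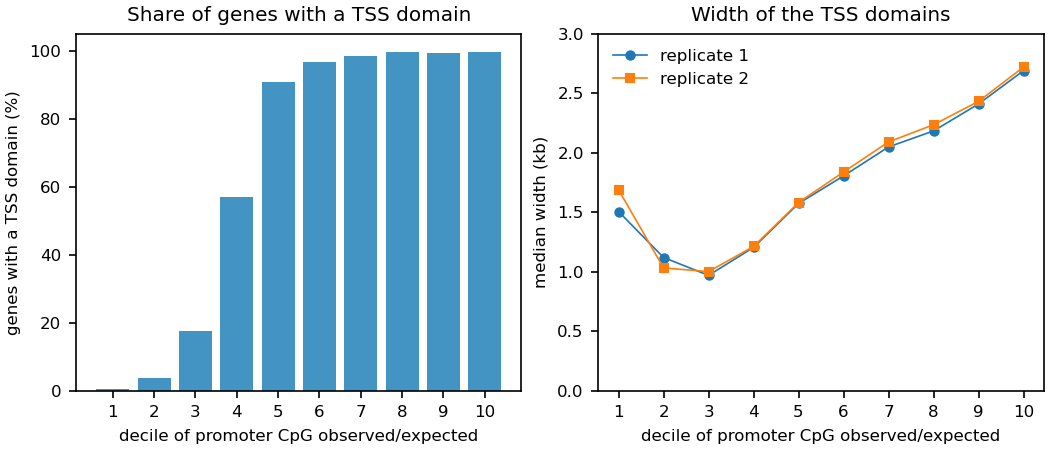
Share of protein-coding genes with a TSS domain in percent (left) and median width in kb of the domains of those genes in each replicate (right), by decile of promoter CpG observed/expected from the lowest (1) to the highest (10). The share goes from 0.684% to 99.6%, and the median width of the highest decile is 2.69 kb and 2.72 kb in the replicates.

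The widest domains of the tissue lay over the posterior parts of the HoxA and HoxD clusters, whose transcription factors pattern the limb along its length. A single domain of the replicated list on chromosome 6 at 52219916 to 52268769 covered Hoxa9, Hoxa10, Hoxa11 and Hoxa13, and also a start site of Hoxa7. In the replicates' own lists, limited to replicated loci, it spanned 47.4 ± 0.107 kb (mean ± SD, n = 2 replicates here and below). A domain of the replicated list on chromosome 2 at 74665143 to 74700328 covered Hoxd9 to Hoxd13. It spanned 35.0 ± 0.304 kb in the replicates' own lists, and that small spread rests on the limit to replicated loci. Without the limit, the domain of replicate 2 ran from 74653765 to 74700183, over Evx2 as well. It then measured 46419 bp, against 35241 bp in replicate 1. All 39 annotated Hox genes had a TSS domain: 11 of HoxA, 10 of HoxB, 9 of HoxC and 9 of HoxD. The clusters differed in level. The median fold enrichment of the HoxA genes was 45.2 (38.7 and 45.8 in the replicates) and of the HoxD genes 27.9 (27.3 and 31.9). It was 6.89 for HoxB (6.77 and 7.39) and 11.5 for HoxC (10.7 and 12.3), so the medians of whole clusters stood further apart than the replicates. Genes under 1 peak share its value. For the anterior genes, numbered below 9, HoxA (26.7 and 22.4) and HoxD (20.6 and 24.3) were not separated. Within the HoxA cluster Hoxa2 had a fold enrichment of 7.38 ± 1.08 and Hoxa10 of 53.0 ± 7.14. In the HoxB cluster the widest domain, shared by Hoxb7 and Hoxb8, measured 4.59 ± 0.173 kb, and Hoxb13 had 0.619 ± 0.280 kb. Hoxc5 and Hoxc10 shared a domain of 6.92 ± 0.0884 kb.

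**Figure D2:**
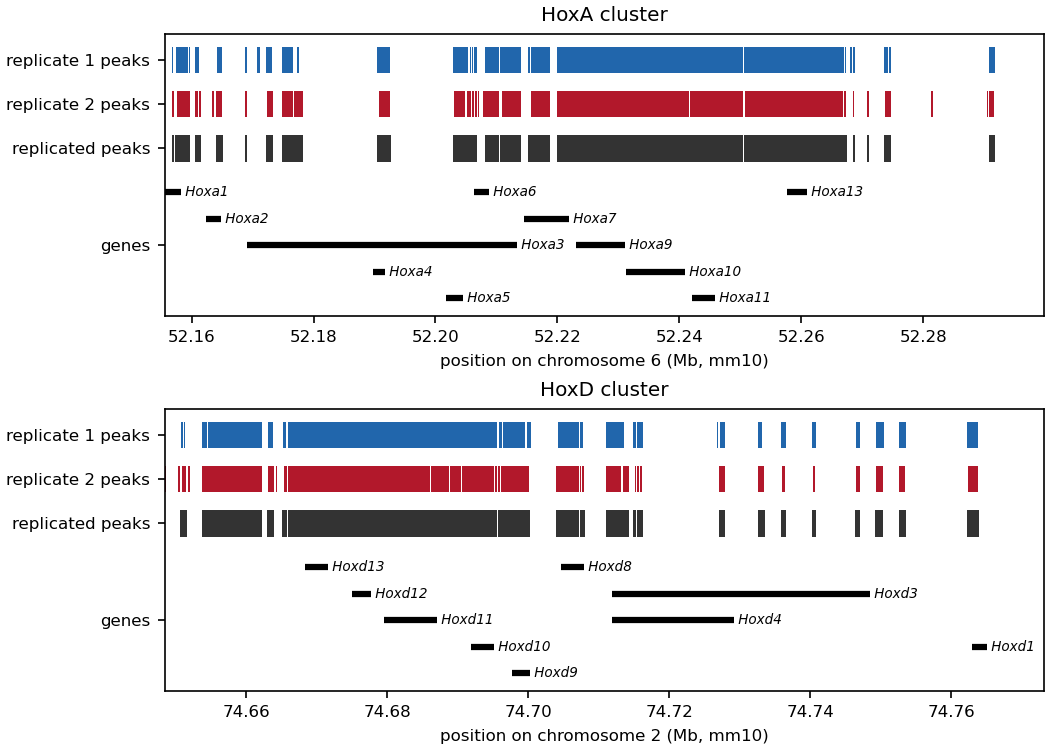
Peaks of each replicate and of the replicated list over the HoxA cluster on chromosome 6 (top) and the HoxD cluster on chromosome 2 (bottom), with positions in Mb on mm10 and bars for the Hox genes. Peaks run almost without a gap from Hoxa9 past Hoxa13 and from Hoxd9 past Hoxd13, and lie in shorter, separate stretches over most anterior genes.

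Genes that pattern the limb carried wide domains as a group. All 28 genes of the limb patterning list had a TSS domain, against 94.4% in CpG-matched random lists (92.3rd percentile, no call). Their median width was 7815 bp (7714 and 7619 bp in the replicates). Matched lists had 1993 bp on average, and none of 10000 reached 7815 bp (percentile 100). In the widest 5% of domains, at least 4655 bp wide, lay 20 of the 28, with 1.29 in matched lists. The widest were at Ptch1, the hedgehog receptor (18.4 ± 0.282 kb, chromosome 13), Lmx1b, a factor of dorsal limb identity (17.4 ± 0.556 kb, chromosome 2), and Tbx5, needed for forelimb outgrowth (16.5 ± 0.403 kb, chromosome 5). Pitx1 and Tbx4, factors of the hind limb, had domains of 12.9 ± 0.422 kb and 12.4 ± 0.105 kb. Shh, the signal of the posterior limb margin, had a narrower domain of 3.03 ± 0.0629 kb and a fold enrichment of 7.51 ± 0.931. The list stood out in width and not in height: its median fold enrichment was 29.5, below the 40.7 of matched lists (0.17th percentile). The 9 genes of the posterior Hox list had a median of 35.0 kb, which rests on the 2 domains described above (percentile 100, but 38.2 by fold enrichment). That median was 40830 bp without the limit to replicated loci and 46419 bp without replicate 1, a setting that also drops the limit. With the limit kept, it was 34811 bp in replicate 2.

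Other genes among the 20 widest domains were Ebf3 (21.6 ± 2.06 kb), Nr2f2 (17.8 kb; 22.6 and 13.1 kb in the replicates, the widest difference among these 20 genes), Zfhx4 (15.9 ± 0.145 kb), Tbx2 (15.9 ± 0.208 kb), Tfap2a (14.5 ± 0.104 kb), Tnrc18 (13.6 ± 0.0177 kb) and Rhof, whose domain of 13.5 ± 0.0141 kb also covered Setd1b. Height picked out other genes. The 10 highest mean fold enrichments belonged to Hsp90aa1, a chaperone (72.0 ± 3.68), Arf1 (71.9 ± 1.24), Rsf1 and Aamdc, which share a domain (71.7 ± 7.22), Nsd2 (70.6 ± 1.72), Arid1a (70.5 ± 1.33), Tax1bp1 (70.0 ± 1.68), Dhx9 (70.0 ± 4.10), Srsf4 (69.7 ± 0.101) and Gm10382, which shares its domain with the polyubiquitin gene Ubc (69.3 ± 2.12). Most of these values lie within the spread of the replicates of each other, so their order is largely unresolved. Of these genes Arid1a had the widest domain, at 8.17 ± 0.319 kb.

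Cartilage and connective tissue genes were also wide. Of the cartilage list, 18 of 19 genes had a domain (99.7th percentile of the share), with a median of 4224 bp (4377 and 4302 bp; 1527 bp in matched lists, percentile 100; 18.3 by fold enrichment). Its widest members were the chondrogenic factors Sox6, whose domain also covered 1110004F10Rik (10980 and 10768 bp in the replicates), Sox5 (8.59 ± 0.158 kb) and Sox9 (7268 and 7169 bp). Col10a1, a collagen of hypertrophic cartilage, had no domain. The tendon and connective tissue list had 13 of 15 genes with a domain (93.9th percentile of the share, no call; 99.35 without replicate 1 and 99.4 without replicate 2) and a median of 4640 bp (percentile 100; 59.8 by fold enrichment), led by Pdgfra, a receptor of mesenchymal cells (11.8 ± 1.20 kb), Osr2 (10.1 ± 0.0863 kb) and Osr1 (7.98 ± 0.0629 kb), with none at Dpt and Tnmd. Of the bone list 8 of 13 genes had a domain, or 61.5% against 56.0% in matched lists (72.4th percentile, no call). Its median was 2310 bp against 750 bp in matched lists (99.9th percentile), and that call was lost with -log10 q of at least 5, with no joining, with unmatched lists and by fold enrichment (95.4, 96.5, 96.6 and 87.2). Col1a1 (7.55 ± 1.20 kb), Runx2 (5.57 ± 0.193 kb) and Col1a2 (5.43 ± 0.492 kb) led, while the mineralisation genes Bglap, Dmp1, Ibsp and Phex had no domain. Among collagen genes as a family 38 of 44 had a domain, with a median of 2548 bp (percentile 100).

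The lists for muscle, skin and vessels had domains more often than matched lists. Of the skeletal muscle list 12 of 18 genes had a domain, or 66.7% against 50.2% in matched lists (98.3rd percentile). That call was lost with TSS windows of 500 bp (79.4) and with unmatched lists (50.1). It was also lost with -log10 q of at least 5 and with the most upstream TSS only. The median width of the list was 766 bp (79.6th percentile, no call), and 1167 bp without replicate 1. Six1 (8.67 ± 0.452 kb), Lbx1 (8.27 ± 0.467 kb) and Mef2c (3.40 ± 0.105 kb) were widest, Myod1, the myogenic regulator, had 1.98 ± 0.417 kb, and the contractile genes Acta1, Actc1, Myh3 and Myh8 had none. Of the skin list 14 of 15 genes had a domain, or 93.3% against 69.6% in matched lists (99.9th percentile; 83.6 with the most upstream TSS only). Its median was 2168 bp (percentile 97.45, under the threshold and so no call). The percentile was 97.55 with q of at most 0.05, but 72.9 with -log10 q of at least 5, 63.7 with no joining and 16.7 by fold enrichment. Tfap2a was followed by Esrp1 (4.28 ± 0.0297 kb) and Grhl3 (3.95 ± 0.0233 kb), and Foxn1 had none. Of the endothelium list 11 of 13 had a domain, or 84.6% against 50.5% (percentile 99.96; 95.9 with the most upstream TSS only and 91.2 with unmatched lists). Its median was 1709 bp (percentile 99.35; 57.1 with the most upstream TSS only, 66.1 with unmatched lists, 96.2 with no joining and 75.2 by fold enrichment). Erg (4.65 ± 0.147 kb), Esam (4.20 ± 0.0410 kb) and Kdr (3.68 ± 0.465 kb) were widest, and Emcn and Tie1 had none. The Schwann cell and melanocyte list had 7 of 10 and a median of 1656 bp (percentile 94.985, no call; 97.6 without replicate 1), with Erbb3 (3.71 ± 0.407 kb), Foxd3 (2.49 ± 0.112 kb) and Pmel, which shares its domain with Cdk2 (2.23 ± 0.0728 kb), and none at Dct, Plp1 and Tyr. Of the blood list 4 of 16 genes had a domain, or 25% against 29.4% in matched lists (30.9th percentile, no call). Its median was 0 bp, which nearly all of its matched lists share, so a low call in width could not arise (49.2th percentile). Runx1 (7.23 ± 0.197 kb), Tal1 (3.40 ± 0.0318 kb) and Klf1 (1.60 ± 0.129 kb) led, and Alas2, C1qa, Csf1r and Epb42 had none.

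Of the 7 lists for organs that a limb lacks, those for eye and ear and for pluripotency and germline were called low in width. The others were not called, and for liver and heart a low call in width was not possible. The liver list had 2 of 12 genes with a domain: Foxa3, whose domain also covered Sympk (4.60 ± 0.0608 kb), and Apoa1 (1.31 ± 0.0898 kb), with none at Afp, Ahsg, Alb and Apob. The heart list had 5 of 12, led by Ryr2 (1.72 ± 0.0615 kb), Tbx20 (1.04 ± 0.0573 kb) and Gata4 (0.991 ± 0.122 kb), with none at Myh6, Myh7, Myl2 and Myl7. Both lists had a median of 0 bp, the lowest value possible, which many of their matched lists share. Their percentiles of width (40.0 and 21.3) could thus not reach a low call. The share with a domain was 16.7% for liver, against 36.5% in matched lists (4.7th percentile, no call). For heart it was 41.7% against 47.9% (27.5th percentile, no call). The pluripotency and germline list had 3 of 13, or 23.1% against 75.1% in matched lists (percentile 0), namely Prdm9 (1.79 ± 0.142 kb), Esrrb (1.61 ± 0.0431 kb) and Dazl (0.917 ± 0.112 kb), and none at Ddx4, Dppa3, Nanog and Piwil2; its median of 0 bp lay below the 1469 bp of matched lists (0.085th percentile; 5.29 with unmatched lists). The eye and ear list had 8 of 11 and a median of 988 bp (percentile 2.125; 2.64 without replicate 1, 7.10 with the most upstream TSS only and 23.6 with unmatched lists, none of which is a call). It was led by Pax6 (2.84 ± 0.0460 kb), Atoh1 (2.71 ± 0.0665 kb) and Vsx2 (2.18 ± 0.00566 kb), and none at Crx, Crygd and Rho. The gut, lung and pancreas list had 9 of 14 and a median of 1322 bp (16.8th percentile), with Sftpc, in a domain shared with Bmp1 (3.84 ± 0.111 kb), Nkx2-1 (3.64 ± 0.0184 kb) and Cdx2 (3.04 ± 0.485 kb), and none at Cdh17, Ins2, Pdx1 and Sftpb. The kidney list had 9 of 11 and a median of 1630 bp over the means of the replicates (34.1th percentile, no call, and 0.175 with no joining). Limited to replicated loci, the medians of the replicates themselves were 1419 and 756 bp. With that limit also dropped, the median was 2039 bp without replicate 1 (76.5th percentile) and 1419 bp without replicate 2 (14.02). The list was led by Emx2 (9.39 ± 0.655 kb), Six2 (6.85 ± 0.489 kb) and Wt1 (2.05 ± 0.886 kb), with none at Slc12a1 and Umod. The forebrain list had 17 of 18, all but Neurod6, and a median of 1936 bp (59.2th percentile, no call). The percentile was 97.9 without the limit to replicated loci. It was 98.3 without replicate 1 and 99.8 without replicate 2, where the limit is dropped too. The list was led by Emx2, Bcl11b (8.20 ± 0.0834 kb) and Dlx2 (5.36 ± 1.48 kb). Its median fold enrichment of 14.8 was below the 38.5 of matched lists (percentile 0).

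**Figure D3:**
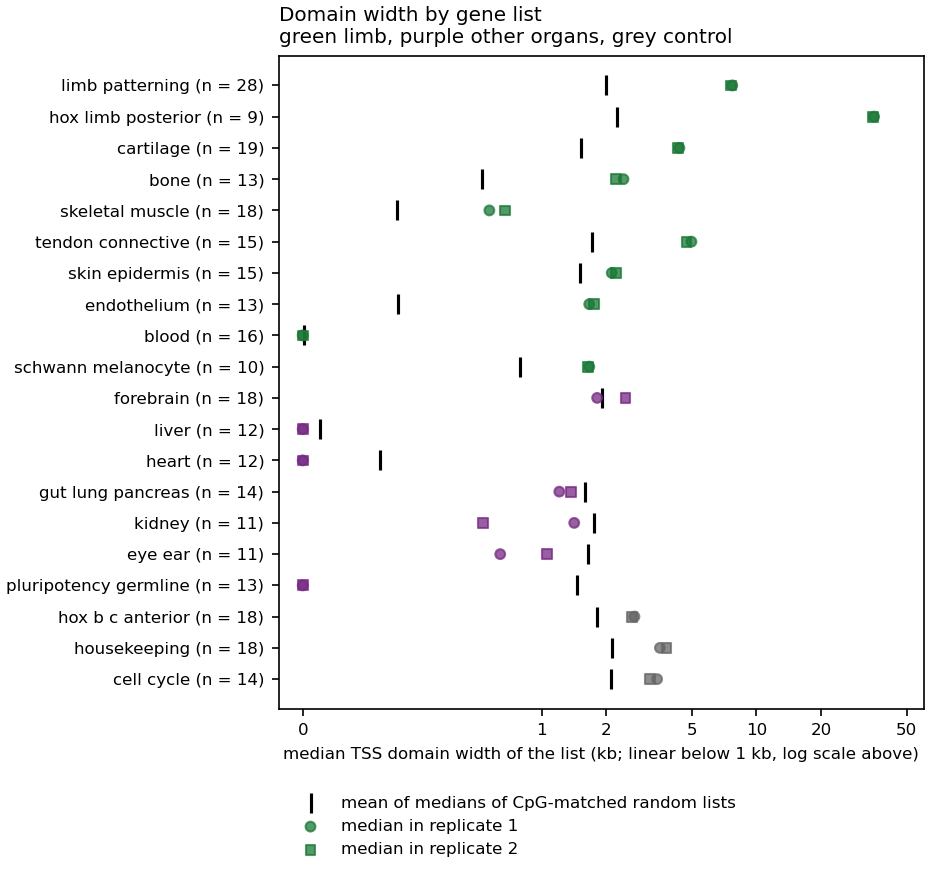
Median TSS domain width in kb of each fixed gene list in replicate 1 (circles) and replicate 2 (squares), with genes without a domain at 0, and the mean of the medians of CpG-matched random lists (vertical marks); the axis is linear below 1 kb and logarithmic above. The limb patterning list sits at 7714 and 7619 bp and its matched lists at 1993 bp, while the liver, heart, blood and pluripotency lists sit at 0 bp.

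Taken over all lists, the 156 limb genes had a median width of 3024 bp and the 90 genes of other organs 838 bp. The difference of 2186 bp lay above all 10000 random reassignments of these genes (percentile 100), of which 95% fell between -786 and 699 bp. A domain was found at 124 of the limb genes (79.5%) and at 52 of the others (57.8%). Of the limb genes 53 were among the widest 5% of domains (34.0%), and of the other organ genes 4 (4.44%). By fold enrichment the limb genes had a median of 21.99 and the other organ genes 5.12, a difference of 16.9 (percentile 100; reassignments from -8.23 to 8.10), while 1 gene of each kind stood among the highest 5%. Promoter CpG content divided both kinds: among genes in the lower 4 CpG deciles 35 of 67 limb genes and 6 of 38 other organ genes had a domain, and in the upper deciles 89 of 89 and 46 of 52. In the upper deciles the marked limb genes had a median width of 5031 bp (4980 and 5133 bp) and the others 1823 bp (1600 and 1975 bp). In the lower deciles the marked genes lay closer, at 2065 bp (2004 and 2214 bp) for limb and 1571 bp (1480 and 1662 bp) for other organs.

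**Figure D4:**
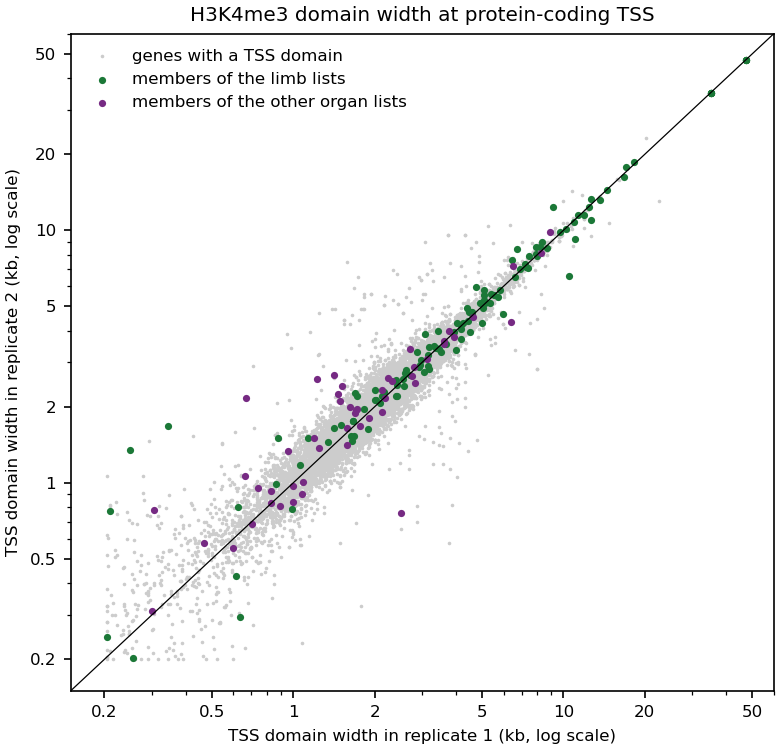
TSS domain width in kb of each protein-coding gene in replicate 1 against replicate 2, on log axes, with members of the limb lists in green, members of the other organ lists in purple, all other genes with a domain in both replicates in grey, and the line of equal width. The widest points are the genes of the HoxA domain at 47.4 kb and of the HoxD domain at 35.0 kb.

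The control lists set the scale, and a high percentile of width was not particular to the limb lists. The housekeeping list had a domain at 18 of 18 genes, with a median of 3890 bp (percentile 100) and a median fold enrichment of 52.1, and its widest members were Rpl13a, sharing a domain with Rps11 (5.11 ± 2.64 kb), Tubb5 (4.93 ± 0.0453 kb) and Tbp, sharing with Psmb1 (4.62 ± 0.386 kb). The cell cycle list had 14 of 14 and a median of 3358 bp (percentile 99.95; 60.8 by fold enrichment), with Ccnd2 (8.25 ± 0.159 kb), Ccnd1 (6.54 ± 0.00212 kb) and Mycn (6.03 ± 0.0474 kb). The HoxB and HoxC list had 18 of 18 and a median of 2633 bp (99.8th percentile), at a median fold enrichment of 9.09 against 35.7 in matched lists, and its width stood at the 16.6th percentile when peaks were not joined and at 94.6 with -log10 q of at least 5. The T-box, Fox and Sox families of transcription factors were wide and the larger Zfp family was not: 14 of 16 T-box genes had a domain (median 2657 bp, 99.9th percentile), 38 of 44 Fox genes (2495 bp, 99.4th percentile) and 19 of 19 Sox genes (2842 bp, 99.8th percentile). The 365 Zfp genes had a median of 1668 bp against 1679 bp in matched lists (40.2th percentile).

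At replicated loci the replicates differed little in width. The median log2 ratio of replicate 2 to replicate 1 was 0.01 for width, with an SD over genes of 0.24. For fold enrichment it was 0.05, with an SD of 0.36. In width 99.0% of genes differed less than 2-fold. The replicated list was derived from both replicates' own lists, so part of this agreement can follow from the limit to it. Without the limit the SD of width was 0.30, and 98.5% of genes differed less than 2-fold. The widths that differed most were wider in replicate 1 at Samd10 (log2 ratio -1.93; 4024 and 1053 bp), Wrap73 (-1.74), Rnf213 (-1.73), Gdf7 (-1.69) and 6430571L13Rik (-1.60). They were wider in replicate 2 at Kremen2 (2.25; 1575 and 7498 bp), Dalrd3 (1.93), Jmjd8 (1.91), Parp10 (1.81) and Zbtb22 (1.81). With 1 value per replicate these differences were not tested.

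Domains away from annotated TSS were narrow. Of 20424 domains, 15434 overlapped a TSS window of any gene, or 75.6% (95% interval 74.97 to 76.2%), against 11.03% on average after random shifts. They held 89.2% of the covered bases and had a median width of 2007 bp, while the other 4990 had 698 bp. Of those 4990, the midpoint of 572 lay in an exon, of 1621 in an intron and of 2797 between genes. The 5 widest domains with no TSS window within 5 kb lay on chromosome 13 at 21166327 to 21173714, between genes and 5.73 kb from the nearest TSS, that of Trim27; on chromosome 3 at 96496835 to 96503652, between genes and 8.11 kb from a small nuclear RNA gene; on chromosome 6 at 51168593 to 51174920, between genes and 94.99 kb from Mir148a; on chromosome 11 at 119052878 to 119058994, between genes and 11.9 kb from Cbx8; and on chromosome X at 12086442 to 12092330, in an intron of Bcor. These positions are relative to GENCODE; in RefSeq, starts of tRNA genes lay within 1 kb of the domains on chromosomes 13 and 3, of Gm32298 by that on chromosome 13 and of Gm46687 by that on chromosome X. Their mean widths in the replicates' own lists were 7070 ± 20.5, 4313 ± 132, 4735 ± 2088, 5928 ± 163 and 5563 ± 152 bp.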

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

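No test in this part was planned. The peaks on scaffolds entered no domain count of the report, and the pooled peaks outside the replicated list entered only the alternatives that take the pooled list. On scaffolds outside the assembled chromosomes lay 12 peaks of the replicated list, 4 of them on scaffolds of chromosome X, 4 on scaffolds of chromosome 4 and 4 on unplaced ones, over 7 scaffolds and all with a partner in each replicate's own list, with a median fold enrichment of 8.42 and a range of 2.96 to 35.7. The pooled list held 5960 peaks that overlap no replicated peak. Their median fold enrichment was 2.72, against 28.4 for the others, and 1588 of them (26.6%) overlapped a TSS window. Of the 5960, 1585 overlapped a peak of replicate 1 alone, 2256 of replicate 2 alone, 60 of both and 2059 of neither.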

How the results depend on the processing

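All tests here were planned except those by strength of the peaks and those on genes alone in their domain, which were chosen after the data were seen. The difference in median width between limb and other organ lists stayed at percentile 100 under each alternative run, from 1722.75 bp with no joining of peaks to 2603 bp with joining up to 3 kb. The limb patterning, posterior Hox, cartilage and tendon lists stayed at percentile 100 of width in every width setting run. By fold enrichment instead of width they did not: limb patterning stood at 0.17, posterior Hox at 38.2, cartilage at 18.3 and tendon at 59.8, bone at 87.2, endothelium at 75.2, cell cycle at 60.8, forebrain and the HoxB and HoxC list at 0, gut, lung and pancreas at 0.51 and kidney at 0.19. The count among the top 5% was then 1 limb gene and 1 other organ gene, though the median fold enrichment was 21.99 for limb and 5.12 for other organ genes (percentile 100). Among the widest 10% of domains were 66 limb and 7 other organ genes.

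The share of peaks with a partner was 88.1% in replicate 1 and 82.9% in replicate 2 with q of at most 0.05, 95.6% and 93.0% with -log10 q of at least 5, 82.4% and 76.3% with overlap of 50% of the peak, and 75.6% and 70.8% with 50% of both peaks. Over 4 equal bins of peaks from the lowest to the highest fold enrichment it was 54.8, 94.7, 100 and 100% in replicate 1 and 39.9, 88.6, 100 and 100% in replicate 2. Spearman's rho of fold enrichment was 0.808 with -log10 q of at least 5. The share of protein-coding genes with a domain was 66.1% with -log10 q of at least 5, 67.2% with the pooled list, 66.0% with loci in both replicates' own lists, 65.9% and 67.0% with TSS windows of 500 bp and 2 kb, 62.8% with the most upstream TSS only, and 66.5 to 66.8% with single replicates. The share of domains at a TSS was 77.1% with -log10 q of at least 5, 69.2% with the pooled list, 77.3% with loci in both replicates' own lists, 77.5% with windows of 2 kb, 72.5% and 77.4% with joining distances of 0 bp and 3 kb, and 70.8 to 72.8% with single replicates.

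Percentiles of width that crossed a threshold were as follows. With -log10 q of at least 5, bone stood at 95.4, kidney at 0.14 and the HoxB and HoxC list at 94.6. With q of at most 0.05, skin stood at 97.55. With the pooled list, forebrain stood at 98.3 and eye and ear at 3.12. With loci in both replicates' own lists, skin stood at 97.7, and with TSS windows of 500 bp at 97.54. With the most upstream TSS only, endothelium stood at 57.1, Schwann cell and melanocyte at 98.8, eye and ear at 7.10 and the HoxB and HoxC list at 94.5. With no joining, bone stood at 96.5, endothelium at 96.2, kidney at 0.175 and the HoxB and HoxC list at 16.6. With joining up to 3 kb forebrain stood at 97.7. With unmatched lists, bone stood at 96.6, endothelium at 66.1, eye and ear at 23.6 and pluripotency at 5.29. Without the limit to replicated loci, forebrain stood at 97.9 and eye and ear at 2.92. Among genes alone in their domain, skin stood at 99.2, eye and ear at 14.8 and the HoxB and HoxC list at 95.8. With single replicates forebrain stood at 98.3 to 99.8, Schwann cell and melanocyte at 95.2 to 97.6 and eye and ear at 2.16 to 2.64. Percentiles of the share of genes with a domain crossed a threshold as follows. With unmatched lists, limb patterning stood at 100, posterior Hox at 98.8, skeletal muscle at 50.1, endothelium at 91.2, blood at 0.015, forebrain at 99.6, liver at 0.03, the HoxB and HoxC list at 99.9, housekeeping at 99.985 and cell cycle at 99.8. With the most upstream TSS only, skeletal muscle stood at 94.2, tendon at 99.6, skin at 83.6, endothelium at 95.9, Schwann cell and melanocyte at 98.955 and liver at 2.29. With TSS windows of 500 bp, skeletal muscle stood at 79.4 and liver at 0.855. Skeletal muscle stood at 93.1 with -log10 q of at least 5, and tendon at 99.1 with the pooled list and at 99.35 to 99.4 with single replicates. The cause of these changes was not tested. Of the widths of named genes, 1412 values under alternatives stayed within the spread of the replicates and 244 did not. The depth of the libraries is unknown, so a gene without a domain is one where the replicated list has none, and other lists can hold a peak there: 124 limb genes had a domain with the replicated list and 130 with the pooled list.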

Other observations

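The gene groups and genes of this paragraph and the next were chosen after their values were seen, so their widths describe those genes and test nothing. All 12 genes of a hedgehog pathway list had a domain, with a median of 5442 bp. Besides Ptch1, Cdon (7.49 ± 0.0354 kb), Gli2 (7.31 ± 0.0552 kb) and Gli3 (7.29 ± 0.0841 kb) led. All 10 frizzled receptor genes had a domain, with a median of 5608 bp and 7 in the widest 5%, led by Fzd2 (8.62 ± 0.0969 kb). All 19 Wnt genes had a domain, with a median of 2704 bp, led by Wnt5a (12.1 ± 0.214 kb). The Notch list had 13 of 13 (3724 bp), led by Hes1 (8.28 ± 0.103 kb). The Bmp genes had 9 of 11 (3655 bp), the Fgf genes 18 of 22 (2217 bp) and the ephrin and ephrin receptor genes 22 of 22 (3138 bp). Immediate early genes, which cells switch on within minutes of a stimulus, had 12 of 12 with a median of 4598 bp.

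In families of transcription factors picked in this way the medians were 9875 bp for Nfia, Nfib and Nfix (their relative Nfic, at 3909.5 bp, was not in that group), 8111 bp for 4 Ebf genes, 5868 bp for 6 Irx genes, 5111 bp for 3 Tshz genes and 3982 bp for 5 Zic genes, all with a domain. Of 67 replication histone genes 60 had one, with a median of 2844 bp. Of 13 myosin heavy chain genes 4 had one, Myh9 (3.71 ± 0.0608 kb) and Myh10 (3.53 ± 0.00495 kb) among them. Wide domains that cover the start of no protein-coding gene lay at 1700021F13Rik on chromosome 5 (11639 bp in the replicated list, though 6106 and 5809 bp in the replicates), at Dleu2 on chromosome 14 (10427 bp; 4822 and 10009 bp), at Mir125b-1 on chromosome 9 (8970 bp), at Malat1 on chromosome 19 (8716 bp) and at Mir199a-2 and Mir214 on chromosome 1 (6771 bp).

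The patterns weighed below had been seen before their tests were chosen, while the values the tests measure had not, except that for CpG content of limb genes, which was chosen after widths by CpG decile had been seen. The wide domains of limb genes were set against 3 technical explanations. For the limb lists taken as 1 set, promoter CpG content was contradicted as the whole cause of the difference in median width. For joining and sharing, that difference cannot separate width from presence of a domain. The limb patterning list, where all 28 genes have a domain, argued against both as the whole cause for that list. No biological explanation was tested, since the design holds 1 group. Joining of separate peaks was removed by taking the widest single peak, and the limb lists still exceeded the other organ lists by 1722.75 bp (percentile 100 of reassignments). Genes without a domain count as 0 bp there, and joining cannot change which genes have a domain (79.5% and 57.8%). The difference thus mixes presence of a domain with its width, and joining was not tested on the marked genes of the whole set alone. In the limb patterning list the median with no joining was 4798.5 bp, at percentile 100 of matched lists. Promoter CpG content was held fixed by reassigning genes between the kinds within CpG decile only, and the difference lay 2179 bp above the mean of the reassignments (percentile 100). Neighbours that share a domain were removed, and the remaining 27 genes of the limb patterning list stayed at percentile 100. The difference between the kinds also did, at 2143 bp, but it again counts genes without a domain as 0 bp. The posterior Hox list has no gene alone in its domain, so sharing stays open for that list.

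Marked X-linked genes had lower fold enrichment than autosomal ones, with a median of 25.3 over 493 genes against 42.7 over 14072, while the ratio of their widths was 0.8998 unmatched and 1.03 (0.970 to 1.09) with CpG matched. Promoter CpG content explains part of the gap at most: against CpG-matched autosomal genes the ratio was 0.698, and the upper limit of the resampled ratio lay under 0.9. That only the active X allele carries the mark in female cells may contribute. As a set, 7 genes known to escape X inactivation had a median of 40.1, at percentile 100 of matched X-linked lists and 99.99 in replicate 1 alone, but 69.1 in replicate 2 alone. A requirement that each replicate pass was added after the medians of the replicates (40.8 and 30.0) had been seen, so this explanation stays open. Copy number of the X in a mix of sexes also stays open, with an upper limit of the ratio of 0.749, because neither the share of males nor the background behind the fold enrichment is given. Of 183 Y-linked genes 4 had a domain, Uty, Ddx3y, Eif2s3y and Kdm5d, with fold enrichments from 11.5 to 16.0.

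The width differences between replicates at the 10 named genes may come from gaps near the joining distance. With peaks joined up to 3 kb apart, 10 of the 10 genes differed by less than 2-fold, and the widest single peak also differed by less than 2-fold in 10 of the 10. Those genes were picked as the extremes at a joining distance of 1 kb, so some shrinkage under any other setting follows from the choice. A pair of the 5 widest domains far from annotated TSS had clusters of tRNA genes nearby, with 7 and 5 genes of the RefSeq annotation within 1 kb. As a hypothesis, tRNA genes may account for part of such domains: of 28 far domains of at least 3 kb, 8 (28.6%) had a tRNA gene within 1 kb, against at most 3.57% after random shifts. Of all 3514 far domains 1.76% had one, so it would be a small part. Starts annotated in RefSeq alone stay open beside it: 10 of the 28 had the start of another RefSeq gene within 1 kb, as had 10.8% of all far domains, against 5.09% on average and at most 5.92% after random shifts.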
